A study of Mus musculus with 2 samples.

How the data were processed

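H3K9ac, an acetylated histone mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the midbrain of mouse embryos at embryonic day 14.5. The labels give 1 group with 2 biological replicates. Replicate 1 was a pool of midbrains from 24 embryos and replicate 2 a pool from 34 embryos, of both sexes. With 1 group of 2 pools no test between conditions is possible, so the comparisons are between lists of peaks, between groups of genes and between genomic windows.

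The authors deposited 4 peak lists on the mm10 assembly: 1 for each replicate, 1 called on both replicates pooled, and a replicated list drawn from the other 3 lists. The texts deposited with the samples state that the replicate 1 list derived from its alignments and 2 further files, and the replicate 2 list from its alignments and 1 further file that replicate 1 shared. The role of the further files, the aligner, the peak caller and its thresholds are not given in the sources used here. Per the labels and the deposited file type, the signal value of each peak is a ratio, its fold enrichment over background as set by the authors' peak caller. The deposited lists also hold −log10 p and −log10 q for each peak, again from the authors' peak caller. The smallest −log10 p was 2.02 in the replicate 1 list and 2.07 in the replicate 2 list. Sequencing depth is unknown, because the lists hold no read counts, and the precision of a single peak's fold could not be given. The fold was used only to rank, describe or bin peaks within a list. Intervals on shares (Wilson or exact Clopper-Pearson, 95%) cover the counting of peaks or genes in these lists and not the variation between embryos.

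Peaks that overlapped or touched were to be merged, but no intervals within a list did. A peak of 1 replicate was found in the other when at least 50% of its length was covered there. The share from 100 random circular shifts of the other list within chromosomes is given beside it. Genes, transcripts and exons came from GENCODE release M21. A promoter was the interval of 1000 bp either side of any annotated transcript start, and a distal peak lay over 1000 bp from any start, or over 5000 bp for motifs and for named distal peaks. Protein-coding genes were counted by symbol, 21911 in all, on chromosomes 1 to 19, X and Y. Peaks on unplaced or unlocalised scaffolds were left out of gene assignment, and were kept in the overlap comparisons, where they counted as distal.

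A set of 27 gene lists covered midbrain patterning, neuronal and glial lineages, other brain regions, blood, vessel and mesenchymal cells, other organs and large gene families. Of their 2257 members, 2256 matched an annotated symbol, and Ahsp did not. Members with and without a replicated promoter peak were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 27 lists. Unstratified odds ratios and their Woolf intervals were computed with 0.5 added to each of the 4 cells, which pulls the ratios of short lists and rare motifs towards 1. An alternative stratified genes by deciles of promoter CpG observed/expected, with the Mantel-Haenszel odds ratio and the Cochran-Mantel-Haenszel chi-square on gene counts, without continuity correction. Promoter CpG was measured in 1000 bp centred on the gene's 5′ end, also for genes marked only at another transcript start. The median width of the widest promoter peak of each list's members was set against 10000 random lists of genes with a promoter peak, drawn with replacement within 5 bins of fold. The permutation p was two-sided and was adjusted over the lists with at least 5 such members. Genes of a list are not independent replicates, and some genes belong to several lists. A list or motif is called here where its adjusted p lay under 0.05.

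Motifs were counted in windows of 500 bp centred on distal replicated peaks and in as many genome windows, matched in bins of 2% GC, that lay over 5000 bp from any peak and any transcript start. Distal peaks had a median width of 430 bp, so many windows reached beyond their peak. Windows of neighbouring peaks were not checked for overlap. Of 800000 positions drawn at random, 508549 gave a usable window. The 16 consensus sequences were searched on both strands and compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment.

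The 27 gene lists, the motifs, the tests of the report, their alternatives and the rule for naming genes were fixed before the data were examined. The rule of 50% of the length of either peak was added later, and so were those tests of the closing section that are named there as chosen after a result was seen. The rule names the 10 protein-coding genes with the highest promoter fold and the 10 with the widest promoter peak. It also names up to 4 members of each list with the highest fold and up to 4 without a peak, the genes nearest to the 10 distal peaks of highest fold, and 19 fixed genes such as En1, Otx2, Th and Foxg1. Any other gene in the text was chosen after its values were seen. The alternatives were an overlap of 1 bp or 80%, −log10 q of at least 5, replicate lists of the same length, promoter windows of 500 and 2500 bp, 1 start per gene, the pooled list, each replicate's list alone, CpG stratification, random lists not matched on fold, and windows matched on CpG count up to 20.

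The procedures were tested on simulated data. With 59.7% of peaks copied from 1 list to another, 59.8% were found. A simulated odds ratio of 8 in the neural progenitor list was called in 57% of runs, and odds ratios of 0.1 in the Hox list and 3 in the zinc finger list in 100% of runs. Lists without a simulated effect were called in 0.348% of tests. Widths multiplied by 2 in the neural progenitor list were called in 95% of runs, against 0.588% of lists without an effect. A motif placed in 10% of 2000 windows gave a mean difference of 9.09 percentage points and was called in 20 of 20 runs, and 2 of 320 motif tests without an implant were called. The list simulation drew each gene independently without regard to CpG content, and the motif simulation compared background windows with each other. These error rates therefore leave out differences in CpG content between real lists or windows. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.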

Results

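H3K9ac was profiled in 2 pools of mouse midbrain at embryonic day 14.5, a stage at which the midbrain holds dividing progenitors, newborn neurons and few mature glia. The replicate 1 list held 47767 peaks covering 27.3 Mb and the replicate 2 list 75082 peaks covering 42.5 Mb. The pooled list held 58319 peaks (40.2 Mb), and the replicated list held 34338 (34.2 Mb, or 1.26% of the genome). Replicated peaks had a median width of 699 bp and a median fold of 5.21 over background, with a highest fold of 53.8. Read depth is unknown. Fold is the authors' own value for each peak and has no replicate error, so it is given here to describe and rank peaks within a list. Promoter folds below are those of the replicated list. The folds in the replicate 1 and replicate 2 lists could differ widely, with 29.5 and 61.7 at Mex3b, 11.3 and 32.7 at Otx2 and 7.59 and 26.9 at Lhx5. At Camk2a they were alike (7.74 and 7.74).

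The 10 genes with the strongest promoter peaks included genes of the actin and tubulin cytoskeleton. Mex3b, which encodes an RNA-binding protein, had the highest promoter fold (51.1; chromosome 7, 82866162 to 82870807). It was followed by Tnpo1, a nuclear import receptor (50.5; chromosome 13, 98924957 to 98927099), Actb, β-actin (49.5; chromosome 5, 142904604 to 142908096), and Skida1 (49.5; chromosome 2, 18044140 to 18051109). Dbn1, an actin-binding protein of neurons, had a fold of 48.9. The peak at Tuba1a, the α-tubulin of developing neurons, had a fold of 48.0 and also lay at a start of the predicted gene Gm49450. Marcksl1 (48.0) and Marcks (47.1), related regulators of actin, and Brsk1 (47.5), a kinase of neuronal polarity, completed the 10 highest. All 10 genes had a promoter peak in both replicate lists.

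The 10 genes with the widest promoter peaks included transcription factor genes and a gene of GABA transmission. Zfhx3, a transcription factor gene, had the widest peak (17883 bp; chromosome 8, 108701036 to 108718918). The next were at the LIM homeobox gene Lhx9 (15782 bp; chromosome 1, 138831898 to 138847679), at Mn1 (14728 bp), at the LIM homeobox gene Lhx1 (11970 bp) and at Slc32a1, the vesicular GABA transporter (11816 bp; chromosome 2, 158605425 to 158617240). A peak of 11694 bp covered starts of both Rhof and Setd1b. Nrn1, a neurite growth factor gene, had a peak of 11134 bp, and the transcription factor genes Ebf3 and Nr2f1 had peaks of 11130 and 11021 bp. All 10 genes had a promoter peak in both replicates. The width depended on the list, and the widest promoter peak at Zfhx3 measured 5336 bp in replicate 1 and 17896 bp in replicate 2. At Lhx1 the widest measured 7287 bp in replicate 1 and 7080 bp in replicate 2. At Setd1b it measured 3630 and 9274 bp, but at Rhof only 630 and 1230 bp, so neither replicate had a wide peak at Rhof.

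Replicated peaks lay at promoters more often than shifted peaks. Of the 34329 replicated peaks on chromosomes, 19983 overlapped a promoter (58.2%, Wilson interval 57.7 to 58.7%), against a mean of 8.84% when the peaks were shifted at random. With 1 transcript start per gene the share was 48.2%. Promoter peaks were wider than the others, with a median of 1101 bp against 407 bp in introns and 459 bp between genes, and they held 77.2% of the covered bases. Introns held 23.4% of the peaks, intergenic sequence 14.3% and exons outside promoters 4.05%. In the replicate 2 list alone the promoter share was 37.1%, and in the replicate 1 list alone it was 51.6%. A replicated promoter peak was present at 14065 of 21911 protein-coding genes (64.2%). Both replicate lists marked 13819 of the protein-coding genes, replicate 1 alone marked 154, and replicate 2 alone marked 817.

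Otx2, En1 and En2, which specify the midbrain, were marked in both pools, and Hoxb1 and Hoxb4 of the hindbrain and spinal cord were not among the replicated promoter peaks. Otx2, which specifies the forebrain and midbrain, had replicated peaks over nearly its whole length. The strongest had a fold of 23.5 and spanned 8850 bp (chromosome 14, 48658787 to 48667636). It lay over a transcript start inside the gene, 6183 bp from the gene's 5′ end, and a peak of fold 15.4 covered the 5′ end itself. En1 and En2, homeobox genes of the midbrain and anterior hindbrain, had promoter folds of 21.3 (chromosome 1, 120602678 to 120610379) and 23.5 (chromosome 5, 28165669 to 28170641). Sox2, a neural progenitor factor, had a fold of 15.8, and Tubb3, neuronal β-tubulin, a fold of 35.1. Gata2 and Gata3, factors of midbrain GABAergic neurons, had folds of 12.4 and 13.1, and Pou4f1, a factor of tectal and red nucleus neurons, 14.2. The dopaminergic regulators Foxa2, Lmx1a, Lmx1b, Pitx3 and Nr4a2 had folds of 6.28, 5.92, 5.92, 9.51 and 12.01, while Th, the rate-limiting enzyme of dopamine synthesis, had no promoter peak in any list. Foxg1, a forebrain factor, Hoxb1 and Hoxb4, hindbrain and spinal cord factors, and Alb, the liver's serum albumin, had no replicated promoter peak. Myod1, a muscle factor, had a weak one (fold 3.23, 439 bp) that was not in the replicate 1 list.

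**Figure D1:**
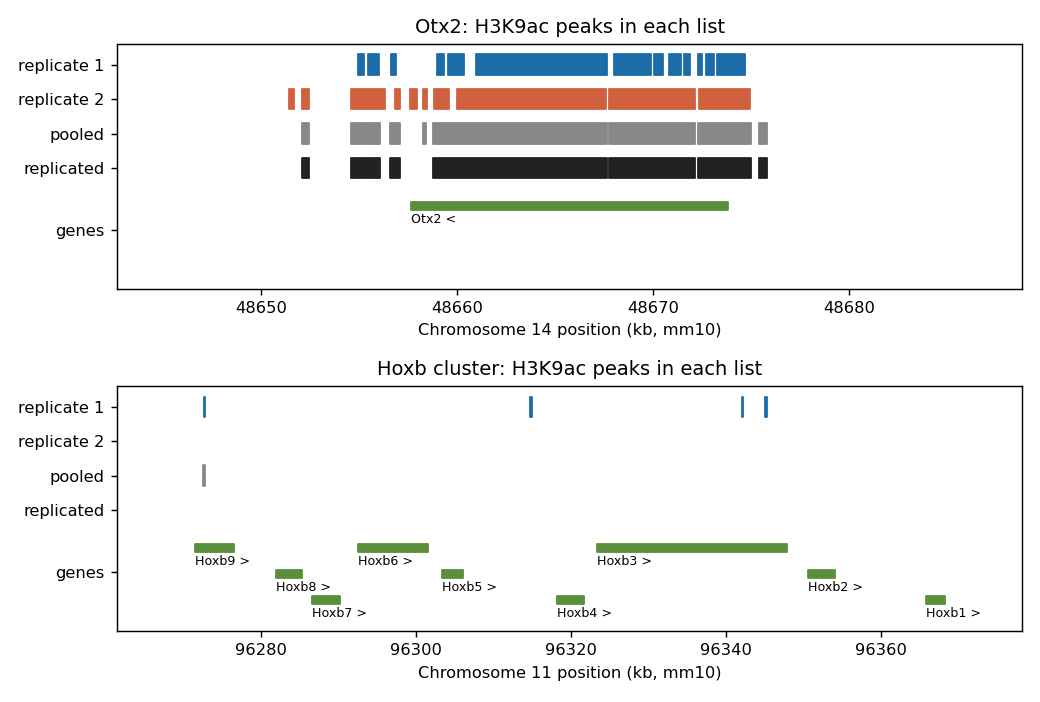
Peaks of the 4 lists along Otx2 on chromosome 14 (upper panel) and the Hoxb cluster on chromosome 11 (lower panel). The horizontal axes give the mm10 position in kb, each bar is a peak drawn to scale, each row is a list, and green bars are genes with arrowheads for their strand. The widest replicated peak at Otx2 spans 8850 bp, and the Hoxb region from Hoxb9 to Hoxb1 has no replicated peak.

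In 5 lists of neural genes nearly all members were marked. Replicated promoter peaks were present at 18 of 19 midbrain patterning factors, 15 of 16 genes of the GABAergic lineage, 18 of 18 of the glutamatergic lineage, 20 of 20 neural progenitor genes and 20 of 20 pan-neuronal genes. They were also present at 20 of 20 cell cycle genes, 77 of 80 ribosomal protein genes and 312 of 365 Zfp-numbered zinc finger genes, against 64.2% of all protein-coding genes. The patterning factor without a peak was Wnt1, a signal of the midbrain-hindbrain boundary (chromosome 15, 98789857 to 98793837), and its pooled-list peak of 379 bp was not listed as replicated. Helt, a selector of GABAergic fate, was the GABAergic gene without a replicated peak. The strongest members were Meis2 (19.4) besides Otx2, En1 and En2 among patterning factors, and Lhx5 (21.7), Ascl1 (19.5), the GABA transporter Slc6a1 (18.8) and the GABA-synthesising enzyme Gad1 (18.7) in the GABAergic list. In the glutamatergic list they were Slc17a6 (22.8), the vesicular glutamate transporter, Lhx2 (22.3), Tcf7l2 (21.9) and Lhx9 (21.6). Msi1 (36.6), Dll1 (23.8), Hes6 (18.3) and Hes5 (17.9) led the progenitor list, and Tubb3, Ncam1 (30.2), Mapt (28.5) and Elavl3 (27.8) the pan-neuronal list. Aurka (19.2), Rrm2 (14.0), Mcm2 (13.6) and Mcm7 (10.9) led the cell cycle list, and the Aurka and Mcm7 peaks also lay at starts of Cstf1 and Ap4m1. Rps19 (33.7), Rps6 (31.0), Rpl9 (29.8) and Rpl19 (29.3) led the ribosomal list, in which Rpl10l, Rpl39l and Rpl3l had no peak. Zfp810 (39.3), Zfp821 (36.6), Zfp618 (36.0) and Zfp292 (34.2) led the zinc finger list, and Zfp345, Zfp352, Zfp366 and Zfp42 were among its members without a peak.

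Hox genes, chemoreceptor genes and the microglia, erythroid, liver, germline, and keratinocyte and gut lists were marked less often than other genes. Peaks were present at 3 of 31 Hox genes, namely Hoxa7 (4.49), Hoxd1 (4.49) and Hoxa1 (4.22), and Hoxa2, Hoxa3, Hoxa5 and Hoxa9 were among those without. The microglia list had 2 of 16, Hexb (13.1) and Aif1 (3.23), and lacked peaks at Cx3cr1, Csf1r, Tmem119 and P2ry12. The erythroid list had 3 of 13, namely Tfrc (17.6), Klf1 (6.997) and Gypa (3.82), and the globin genes Hba-a1, Hba-a2, Hbb-bt and Hbb-bs had none. The liver list had 2 of 18, Apoh (16.7) and Apoa1 (6.81), where the Apoh peak also lay at a start of Prkca, and Afp, Apoa2 and Apob were unmarked. The germline list had 1 of 16, Dazl (7.18), with Ddx4, Sycp1, Sycp3 and Prm1 unmarked. The keratinocyte and gut list had 4 of 16, with Lor (21.5), Krt1 (15.1) and Krt10 (10.8), genes of the differentiated epidermis, and Cdx1 (3.23) marked, and Krt5, Krt14, Flg and Ivl unmarked. The Lor peak lay over the gene's body, 734 bp from its 5′ end (chromosome 3, 92080083 to 92082408). Of 1092 olfactory receptor genes only Olfr94 (13.3) had a peak, and of 326 vomeronasal receptor genes only Vmn1r4 (16.1), whose peak also lay at a start of Nt5c3. Olfr1, Olfr10, Olfr1000, Olfr1002, Vmn1r1, Vmn1r10, Vmn1r100 and Vmn1r101 were among the receptor genes without a peak.

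The remaining 11 lists did not pass the test in either direction with the settings fixed for the report. The dopaminergic list had peaks at 17 of 20 genes and lacked them at Th, Aldh1a1 and Corin. It shared Otx2, En1, En2, Lmx1a and Lmx1b with the patterning list, so its test is not independent of that list's. The oculomotor and serotonergic list had 9 of 11, with Isl1 (5.38), Fev (4.31) and a peak shared by the cholinergic genes Chat and Slc18a3 (4.67), and lacked Phox2b and Tph2. Forebrain genes were marked at 14 of 20, led by Bcl11b (22.8), Emx2 (13.3), Satb2 (9.15) and Six3 (8.07), and Foxg1, Arx, Nkx2-1 and Tbr1 were unmarked. Oligodendrocyte precursor genes were marked at 9 of 10, led by Lhfpl3 (12.6), Ptprz1 (9.96), Bcan (6.64) and Pdgfra (4.67), without Gpr17. Myelinating oligodendrocyte genes were marked at 5 of 12, including Mbp (20.3), Cnp (8.25), Myrf (6.49) and Mal (6.10), and not at Plp1, Mog, Mag or Mobp. Astrocyte genes were marked at 7 of 12, including Nfib (21.9), Glul (21.5), Slc1a2 (19.002) and Nfia (16.1), and not at Gfap, Aqp4, Aldh1l1 or S100b. The endothelial list had 9 of 16, led by Mfsd2a (12.7), Kdr (8.96), Egfl7 (8.43) and Esam (6.69), without Pecam1, Cdh5, Tek and Tie1. The mural, meningeal and mesenchymal list had 13 of 19, led by Twist1 (7.89), Prrx2 (7.18), Prrx1 (7.09) and Foxc1 (6.82), without Rgs5, Acta2, Col3a1 and Dcn. The choroid plexus and ependyma list had 7 of 12, with Otx2, Kl (8.97), Clic6 (6.57) and Rsph1 (6.01) marked and Ttr, Folr1, Aqp1 and Ccdc153 unmarked. The heart and skeletal muscle list had 7 of 18, led by Ckm (5.48), Myf6 (5.21), Myh7 (4.13) and Des (3.41), without Myh6, Myl2, Myl7 and Tnnt2. Neuropeptide and late neuronal genes had 17 of 20, led by Bdnf (23.1), Arc (10.8), Camk2a (9.86) and Syt2 (9.86), without Vip, Nts and Gabra6. The peaks of Hes5, Rpl9, Ckm and Glul also lay at starts of Pank4, Lias, Klc3 and Teddm2, and those of several other named genes at starts of predicted or noncoding genes. The peaks named for Gad1, Satb2, Six3, Bcan, Pdgfra, Nfib, Nfia, Aif1, Egfl7, Esam, Prrx2, Clic6, Apoa1, Krt1, Krt10, Bdnf, Syt2 and Olfr94, like that of Otx2, lay at annotated starts over 1000 bp from the gene's 5′ end. Genes named for any list as unmarked lacked a replicated promoter peak, but some had one in a replicate's own list. Nkx2-1 (folds 3.15 and 3.41 in replicate 1 and replicate 2) and Myl2 (3.73 and 3.41) had one in both. Helt (5.11) and Afp (5.37) were among those with one in replicate 2 only.

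By Fisher's exact test, two-sided and adjusted over 27 lists, 8 lists were marked more often than other genes and 8 less often. The odds ratio was 6.89 for patterning factors (95% interval 1.30 to 36.4; adjusted exact p = 0.00615), 5.77 for the GABAergic list (1.08 to 30.8; 0.0266), 20.7 for the glutamatergic list (1.25 to 343; 0.00154) and 22.9 for the progenitor, pan-neuronal and cell cycle lists (1.39 to 379; 5.12e-04 for each). It was 12.4 for ribosomal genes (4.25 to 36.2; 7.22e-11) and 3.31 for zinc finger genes (2.47 to 4.43; 8.18e-19). It was 0.0683 for Hox genes (0.0225 to 0.207; 2.15e-09), 0.0960 for microglia (0.0251 to 0.368; 1.02e-04), 0.186 for erythroid cells (0.0554 to 0.623; 0.00589), 0.0844 for liver (0.0223 to 0.319; 1.88e-05), 0.0539 for germline (0.0101 to 0.288; 9.68e-06) and 0.201 for keratinocytes and gut (0.0683 to 0.589; 0.00511). It was 6.6e-04 for olfactory and 0.00246 for vomeronasal receptors. These 16 calls held in each replicate's list alone, but a change of 1 marked gene moved the odds ratios of short lists widely. In the replicate 1 and replicate 2 lists alone they were 7.01 and 19.4 for patterning factors, 5.88 and 16.4 for the GABAergic list, 6.64 and 18.4 for the glutamatergic list and 7.39 and 20.4 for the cell cycle list. They were 0.147 and 0.237 for microglia, 0.0486 and 0.202 for liver, 0.0927 and 0.103 for Hox genes and 0.00248 and 0.00136 for olfactory receptors. Among the lists that did not pass, the dopaminergic list had an odds ratio of 2.79 (0.886 to 8.80; adjusted exact p = 0.0874) and the muscle list 0.363 (0.145 to 0.912; 0.0720). The muscle list was called as marked less often in 4 alternatives (adjusted exact p = 2.27e-04 to 0.0465), but had an odds ratio of 1.04 with CpG strata. In the pooled list the dopaminergic (3.81; adjusted exact p = 0.0433), oculomotor and serotonergic (11.8; 0.0306) and oligodendrocyte precursor (10.8; 0.0306) lists were called as marked more often, and in the replicate 2 list alone the dopaminergic list was (3.68; 0.0486).

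Several of these calls were lost when genes of like CpG content at the gene's 5′ end were compared. With genes stratified by CpG decile, the Cochran-Mantel-Haenszel chi-square on gene counts no longer called the patterning (18 genes marked, 16.9 expected; adjusted p = 0.440), GABAergic (15, 14.1 expected; 0.546), progenitor (20, 17.4 expected; 0.0594), cell cycle (20, 19.1 expected; 0.440) and ribosomal (77, 73.8 expected; 0.125) lists, nor the microglia (2, 4.66 expected; 0.213), erythroid (3, 3.35 expected; 0.909), liver (2, 5.36 expected; 0.125) and keratinocyte and gut (4, 5.57 expected; 0.440) lists. The glutamatergic (0.0203), pan-neuronal (0.00156), zinc finger (1.59e-06), Hox (2.62e-45), germline (1.76e-08), olfactory (1.55e-37) and vomeronasal (4.45e-09) lists were still called, and the late neuronal list was called as marked more often (17, 12.9 expected; 0.0262). This chi-square is a large-sample approximation, and short lists had few genes per decile, so their p are rough and can be too small. The counts were 3 marked against 26.4 expected for Hox genes, 1 against 9.66 for germline genes and 18 against 15.2 for glutamatergic genes. No exact stratified test was run, so the glutamatergic and late neuronal calls are uncertain. With 1 start per gene the GABAergic list was no longer called (odds ratio 3.81, adjusted exact p = 0.0593), and the progenitor and pan-neuronal odds ratios were 8.54 each with both lists still called.

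**Figure D2:**
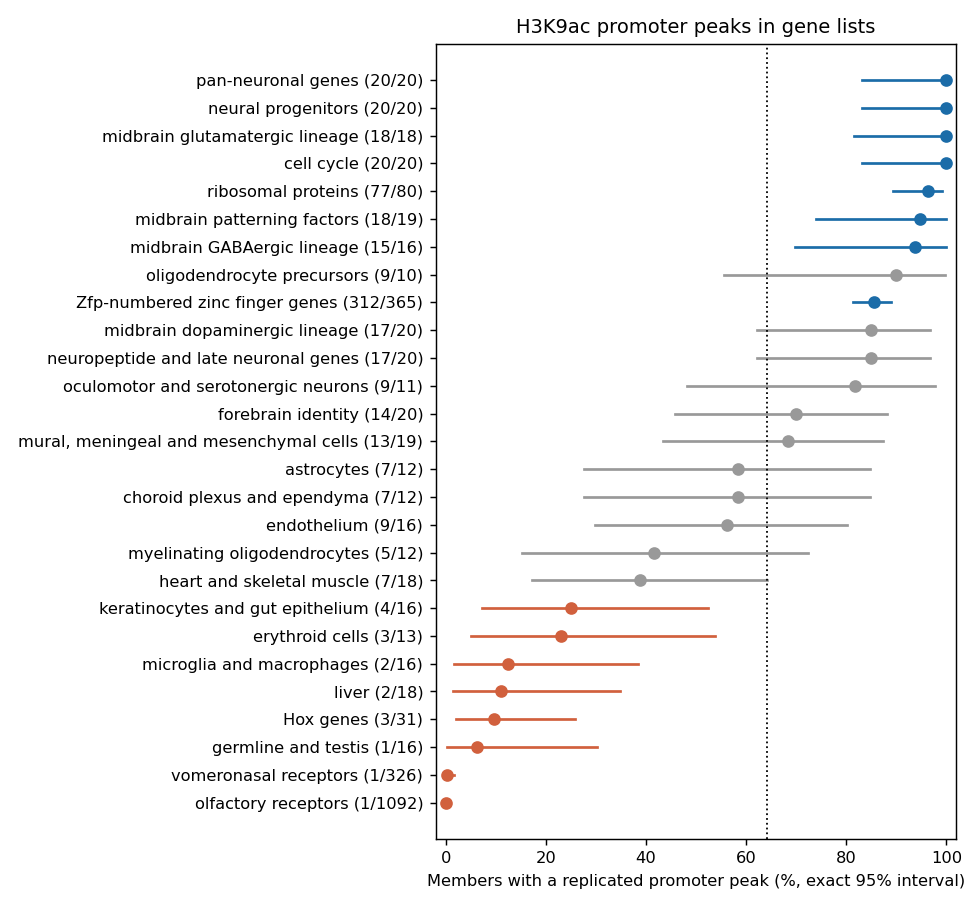
Share of the members of each of 27 gene lists with a replicated H3K9ac promoter peak. The horizontal axis is the percentage of members, points are shares, bars are exact 95% intervals, and the dotted line marks the share of all protein-coding genes (64.2%). Lists in blue were marked more often than other genes, lists in orange less often, and lists in grey passed the test in neither direction. The pan-neuronal, progenitor, glutamatergic and cell cycle lists stand at 100%, and the receptor lists stand below 1%.

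Genes of the midbrain GABAergic and glutamatergic lineages, of progenitors and of the pan-neuronal, patterning and astrocyte lists had wide promoter peaks. The median width was 4639 bp in the GABAergic list, against 1462 bp in random lists of the same fold, and 3962.5 bp against 1425 bp in the glutamatergic list. It was 3150.5 bp against 1443.5 bp for progenitors, 2967 bp against 1829 bp for pan-neuronal genes, 2460 bp against 1136 bp for patterning factors and 3221 bp against 1595 bp for the 7 marked astrocyte genes. Single genes with wide peaks in these lists were Lhx5 (8877 bp), Gad1 (8659 bp), Tcf7l2 (11005 bp; chromosome 19, 55894982 to 55905986), Hes5 (6068 bp), Mapt (5072 bp), En1 (7702 bp) and Nfib (6767 bp), the last a factor that also acts in neurons and progenitors. The wide peak of Tcf7l2 lay at an annotated start far from the gene's 5′ end. That end was covered by the gene's strongest peak (chromosome 19, 55741298 to 55747581). The list of Zfp-numbered genes had narrower peaks, 1449 bp against 1599 bp.

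The first 5 of these lists had a two-sided permutation p of 2e-04, the smallest that 10000 random lists can give, and an adjusted p of 7.6e-04. Astrocyte genes had an adjusted permutation p of 0.00253 and zinc finger genes of 0.00380. The other 12 tested lists did not pass. Their medians were 1224 bp against 1057 bp for dopaminergic genes, 994 bp against 942 bp for cell cycle genes, 1664 bp against 1839 bp for ribosomal genes, 640.5 bp against 909.5 bp for forebrain genes, 945 bp against 896 bp for late neuronal genes and 1056 bp against 858 bp for oligodendrocyte precursor genes. They were 774 bp against 999 bp for myelinating oligodendrocyte genes, 976 bp against 907 bp for choroid plexus, 882 bp against 920 bp for endothelium, 747 bp against 756 bp for oculomotor and serotonergic genes, 625 bp against 751.5 bp for mural, meningeal and mesenchymal genes and 562 bp against 755 bp for muscle genes. In the replicate 1 list alone the patterning factors (934 bp against 758 bp) and the zinc finger genes (1075.5 bp against 1124.5 bp) were no longer called, each with an adjusted permutation p of 0.334. The other 5 wide lists were still called there, with smaller medians of 2263 bp against 1013 bp for the GABAergic list, 3159 bp against 986 bp for the glutamatergic list, 1783.5 bp against 968 bp for progenitors, 2355 bp against 1299 bp for pan-neuronal genes and 2141 bp against 1073 bp for astrocyte genes. The zinc finger call was also lost against random lists not matched on fold (ratio of medians 0.972, adjusted permutation p = 0.502). With 1 start per gene the median was 3153.5 bp against 1379.25 bp for the GABAergic list and 3168.5 bp against 1347.5 bp for the glutamatergic list. For progenitors it was 3261 bp against 1431 bp, and these lists were still called. No random lists were matched on CpG content or on the number of starts per gene, so their part in the widths was not tested.

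**Figure D3:**
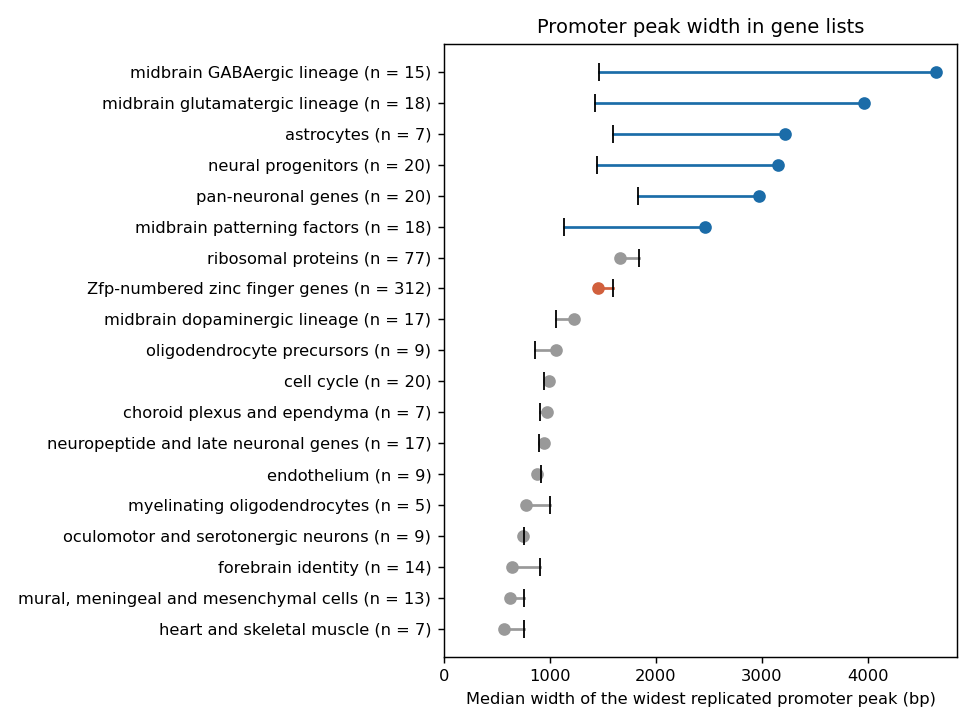
Median width of the widest replicated promoter peak in gene lists with at least 5 marked members. The horizontal axis is the width in bp, points are list medians, and black ticks are the medians of 10000 random lists of the same size and fold, joined to the point by a line. Lists in blue were wider, the list in orange was narrower and lists in grey passed the test in neither direction. The GABAergic list has the widest median, 4639 bp.

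Away from promoters, 8495 replicated peaks (24.7%) lay over 5000 bp from any transcript start, with a median width of 430 bp and a median fold of 3.64. The strongest had a fold of 27.2 and lay between genes, 11440 bp from Gpr161, a receptor of the Hedgehog pathway (chromosome 1, 165280779 to 165284349). The next lay between genes 74686 bp from Chd2 (fold 24.9; chromosome 7, 73616516 to 73619462) and in an intron of Gm12446, 37851 bp from Foxe1 (fold 24.7; chromosome 4, 46304682 to 46305758). The others of the 10 strongest lay nearest to Ddit4 (24.7), Tex44 (24.4), Spag6 (24.4), Arhgap32 (24.3), Cbx8 (24.0), Sox17 (23.1) and Foxn2 (22.7). The distance to the nearest protein-coding start ran from 11440 bp at Gpr161 to 183108 bp at Foxn2. All 10 peaks were in both replicate lists.

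Of 16 motifs, 10 were more frequent in windows centred on distal peaks than in matched windows and 1 was less frequent. The homeodomain core TAATTA was present in 12.3% of 8368 distal windows and 5.52% of GC-matched windows (odds ratio 2.39, 95% interval 2.13 to 2.68). The SOX-type sequence ACAAAG was present in 42.1% against 30.6% (1.65, 1.54 to 1.75) and the SOX sequence ACAATG in 24.0% against 17.6% (1.48, 1.37 to 1.60). The E-box CAGCTG, bound by proneural factors, was present in 37.8% against 27.7% (1.58, 1.48 to 1.69). Octamer sites of POU factors were present in 4.06% against 2.03% (2.04, 1.69 to 2.46), RFX sites in 1.03% against 0.203% (4.98, 2.98 to 8.34) and CTCF sites in 1.41% against 0.442% (3.19, 2.21 to 4.61). OTX/PITX sites (14.9% against 11.9%; 1.30, 1.18 to 1.42), GATA sites (20.4% against 17.0%; 1.25, 1.16 to 1.35) and forkhead sites (6.45% against 4.66%; 1.41, 1.23 to 1.61) were also more frequent. AP-1 sites were less frequent (6.70% against 7.93%; 0.834, 0.742 to 0.937).

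The adjusted p of Fisher's exact test, two-sided over 16 motifs, was 9.48e-53 for TAATTA, 1.23e-52 for ACAAAG, 4.81e-43 for CAGCTG, 7.1e-24 for ACAATG, 7.55e-07 for forkhead and 0.00357 for AP-1 sites. The E-box CATCTG (37.0% against 35.7%; 1.06, 0.994 to 1.13), NFI sites (1.29, 0.318 to 5.20), REST sites (2.11, 0.688 to 6.49) and the control sites of HNF4 (0.959, 0.644 to 1.43) and MEF2 (3.29, 0.994 to 10.9) did not pass with the settings fixed for the report. Peak windows held more CpG than their matched windows (11.8 against 8.26 per 500 bp), and with CpG matched as well the forkhead odds ratio was 0.933 (adjusted exact p = 0.402) and the AP-1 odds ratio 1.04 (0.648). The AP-1 call was lost in every alternative. RFX sites were called in all 5, with odds ratios from 2.99 for distal peaks over 1000 bp from a start to 7.41 with CpG-matched windows. CATCTG was called as more frequent in 4 of 5 alternatives, all but distal peaks over 1000 bp from a start (1.07 to 1.12). REST sites were called with the pooled list (3.46), the replicate 2 list alone (2.03) and distal peaks over 1000 bp from a start (3.55), and the MEF2 control was called with the pooled list (2.26), the replicate 2 list alone (3.14) and distal peaks over 1000 bp from a start (3.62).

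**Figure D4:**
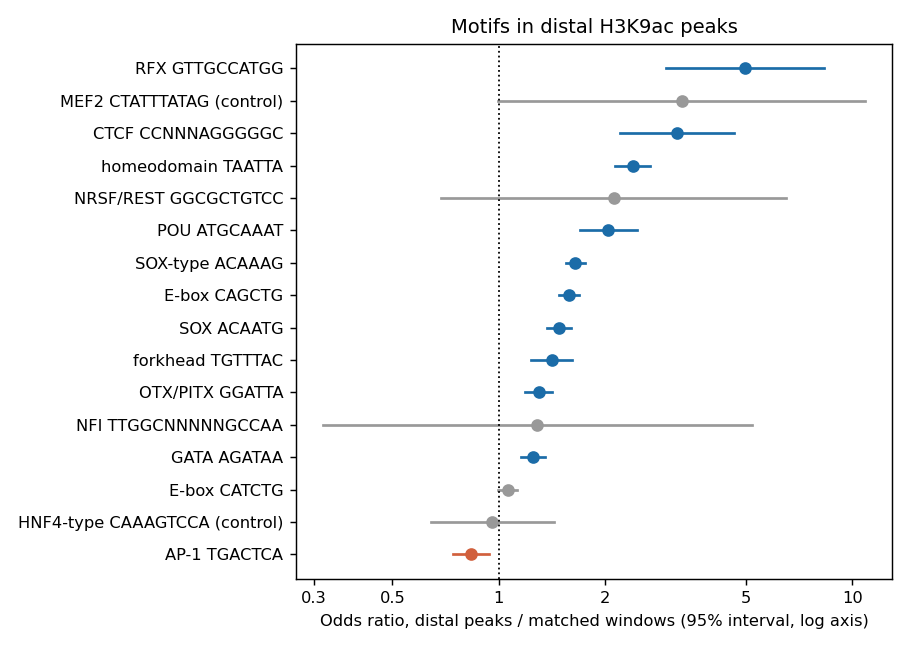
Odds ratio of each of 16 motifs in 8368 distal H3K9ac windows of 500 bp against as many GC-matched windows. The horizontal axis is the odds ratio on a log scale, points are odds ratios, bars are 95% intervals, and the dotted line marks 1. Motifs in blue were more frequent in the peak windows, the motif in orange less frequent, and motifs in grey passed the test in neither direction. In these windows the RFX motif has the highest odds ratio, 4.98, and AP-1 the lowest, 0.834.

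The 2 replicates shared most of their strong peaks, and the weak peaks of replicate 2 were seldom found in replicate 1. The promoters of Mex3b, Actb and Tubb3 had peaks in both lists, with widths of 3483, 2004 and 3165 bp in replicate 1 and 4561, 3071 and 5224 bp in replicate 2. Hoxa1, Myod1, Myf6, Apoa1 and Chat were among the 817 protein-coding genes with a promoter peak in replicate 2 only. Lor was also without a replicate 1 promoter peak, but a replicate 1 peak lay just outside its promoter window. Of the replicate 1 peaks, 32289 of 47767 were found in replicate 2 (67.6%, Wilson interval 67.2 to 68.0%), against 1.66% after random shifts. Of the replicate 2 peaks, 23112 of 75082 were found in replicate 1 (30.8%, 30.5 to 31.1%), against 1.08%.

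The share found rose with fold in both lists. In the lowest decile of fold, 37.6% of replicate 1 peaks and 6.31% of replicate 2 peaks were found in the other list, and in the highest decile 100% and 99.3%. At −log10 q of at least 5 in both lists, the share of replicate 2 peaks found rose to 55.05%. When an overlap of 80% was required it fell to 15.4%.

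**Figure D5:**
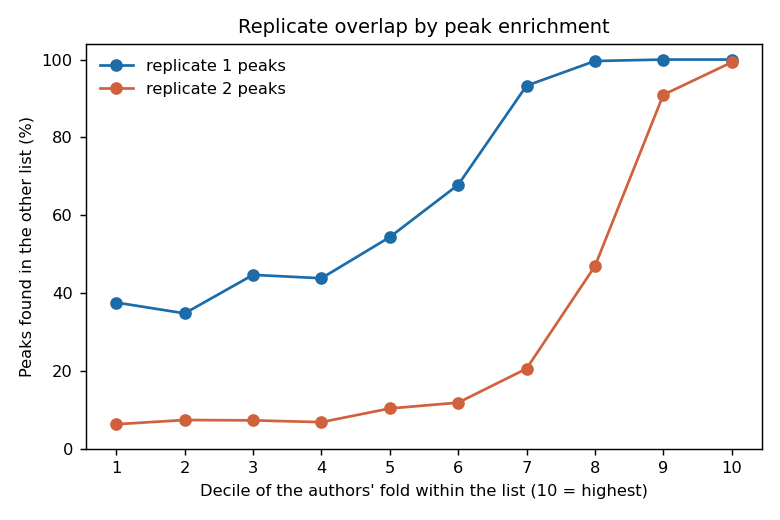
Share of each replicate's H3K9ac peaks found in the other replicate's list, by decile of fold within the list. The horizontal axis is the decile, with 10 the highest, the vertical axis is the percentage of peaks with at least 50% of their length covered, and each line is 1 replicate's list. The replicate 2 line runs from 6.31% to 99.3%.

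Promoter peaks recurred more often than distal peaks. In replicate 1, 89.2% of promoter peaks and 44.6% of peaks over 1000 bp from any start were found in replicate 2 (odds ratio 10.2, 95% interval 9.75 to 10.7), with peaks on scaffolds outside the chromosomes counted among the latter. In replicate 2, 59.6% and 13.8% were found in replicate 1 (9.21, 8.89 to 9.54). The p of Fisher's exact test, two-sided, was too small to be represented in either list, and the test compares these 2 libraries only. Stratified by quintiles of fold and width, the odds ratios fell to 3.55 for replicate 1 and 1.87 for replicate 2 (Cochran-Mantel-Haenszel chi-square p = 2.39e-136 for replicate 2).

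The replicated list was longer than the set of pooled peaks found in both replicates. Of 58319 pooled peaks, 22954 (39.4%) had at least 50% of their length covered in each replicate list, 5567 in replicate 1 only, 22988 in replicate 2 only and 6810 in neither. The authors listed 34338 pooled peaks (58.9%) as replicated, which included 22951 of those found in both and 11387 others. With 50% of the length of either peak of a pair as the rule, chosen after seeing the data, 27199 pooled peaks were found in both, 27083 of them were listed as replicated, and 7255 listed peaks were not among them. Listed peaks had a median fold of 5.21 and a median width of 699 bp, against 2.87 and 225 bp for the pooled peaks not listed.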

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

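The tests on exons and on epidermal genes, and the CpG stratification of the genes marked in replicate 2 only, were chosen after the results they bear on had been seen, and the other tests were set down before. The replicated list held 9 peaks on scaffolds outside chromosomes 1 to 19, X and Y, which were left out of the promoter share and of the gene and motif comparisons. Of these, 5 lay on an unlocalised scaffold of chromosome X (highest fold 9.68), 3 on an unplaced scaffold (2.17) and 1 on an unlocalised scaffold of chromosome 4 (13.6).

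The replicate 2 list was longer than the replicate 1 list, and 45886 of its peaks shared no base with a replicate 1 peak. A tail of weak calls is a candidate explanation. Of these peaks, 71.3% (exact interval 70.9 to 71.7%) lay in the lower-ranked 50% of replicate 2's folds. This share lay between the bounds of 80% and 60% set for and against it. The unmatched peaks were over 50% of the 75082, so the lower-ranked 50% could not hold them all. The bound of 80% could hardly be met, and missing it decides nothing. Of the lower-ranked peaks 87.1% shared no base with replicate 1, against 35.1% of the upper-ranked ones. The highest fold among the unmatched peaks was 11.9. The explanation stays open. Other cell types or regions in the replicate 2 pool were tested on forebrain, Hox, vessel, mesenchymal, blood and choroid plexus genes without a replicate 1 promoter peak: 15 of 77 had a replicate 2 peak, against 802 of 7861 other genes (odds ratio 2.18, 1.25 to 3.82; exact p = 0.0131, two-sided), which met the condition set down for this explanation. A stratification by CpG decile, added after that result, gave an odds ratio of 0.985 (0.554 to 1.75), and because of it this explanation is held open here, although the written condition was met. Depth could not be weighed, since it is unknown, and the pools differed in embryos (24 and 34).

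Marker genes of other cell types carried promoter peaks, 46 of 144 across the myelin, microglia, vessel, mesenchymal, erythroid, liver, muscle, germline and epithelial lists. The bound for CpG-rich promoters marked in every cell type was at least 80% of marked markers in the upper 50% by promoter CpG. Of the marked markers 50% lay there (23 of 46; exact interval 34.9 to 65.1%), short of 80% but not below the 50% set against it. Of the 98 unmarked markers 8.16% lay there. Among all marked protein-coding genes the share was 75.3%, itself under 80%, so missing that bound does not count against the explanation. The upper 50% held 31 markers, of which 74.2% were marked, against 96.7% of all genes there. Blood and vessel cells in the tissue might add peaks at CpG-poor promoters, but 18.4% of their 38 CpG-poor markers were marked (7.74 to 34.3%), against 31.7% of other CpG-poor genes, and the interval holds that value. Both tests used the CpG at the gene's 5′ end, while the strongest peaks of some marked markers, such as Egfl7, Esam, Krt1 and Krt10, lay at other starts. Neither test excluded its explanation as part of the pattern, and with 1 group in the design no biological explanation by a difference between groups was tested.

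Lor, Krt1 and Krt10, genes of the differentiated epidermis, carried strong peaks while Krt5, Krt14 and Trp63 carried none. A candidate explanation is that CpG-dense exons carry peaks: in exons of at least 200 bp over 1000 bp from any start, 221 of 1142 CpG-dense exons (19.4%) overlapped a peak that was itself over 1000 bp from any start, against 266 of 6675 other exons of at least 55% GC (3.99%; odds ratio 5.78, 4.78 to 6.999), above the bound of 3. That bound was written with the values in all other exons (22.6% against 2.11%, odds ratio 13.5) already seen, and it replaced a comparison within keratin, loricrin and chemoreceptor genes that held 1 CpG-dense exon, with a peak, against 1 of 705 others with a peak. The explanation leaves part of the pattern open, since the peaks of Lor, Krt1 and Krt10 reached promoter windows, which the test left out, the Krt1 peak had a CpG observed/expected of 0.506, under the 0.6 that defined a dense exon, and the Krt10 peak had 54.4% GC, under 55%. Epidermal cells in the tissue also stay open, with 6 of 15 basal epidermis genes marked (40%, exact interval 16.3 to 67.7%) against 64.2% of other genes. The 6 marked genes had a promoter CpG observed/expected of 0.522 to 0.754, and all unmarked ones but Tfap2c (0.688) had 0.139 to 0.354. The share of other genes was not matched on CpG, so the test cannot separate epidermal cells from CpG content.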

How the results depend on the processing

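The rule of 50% of the length of either peak was chosen after seeing the data, as were the tests so named in the closing section. No paired analysis was possible because the design has 1 group. Intervals as listed gave the same values as merged ones, since none touched. The odds ratio of promoter against distal peaks in replicate overlap kept its direction and its call in all 8 alternatives (1.87 to 12.9), and the number of protein-coding genes with a promoter peak ran from 13230 to 14636 over 7. The 6 lists called wider held in every alternative except the replicate 1 list alone, which lost the patterning factors. Depth is unknown, and its effect on the lists could not be examined. Unless a construction is named, the cause of a change was not tested.

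The shares of replicate 1 and replicate 2 peaks found in the other list were 72.9% and 38.9% at 1 bp, 58.9% and 15.4% at 80% of the length, 97.8% and 55.05% at −log10 q of at least 5, and 64.0% and 44.8% with lists of the same length. The share of pooled peaks in both lists was 47.1% at 1 bp, 17.2% at 80%, 53.8% at −log10 q of at least 5 and 46.6% with the length of either peak. The share of peaks at promoters was 53.9% with 500 bp, 67.5% with 2500 bp, 42.3% in the pooled list, 70.5% at −log10 q of at least 5, 48.2% with 1 start per gene, and 37.1% to 51.6% in the list of a single replicate. A wider window or a smaller overlap can only raise such a share by construction.

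Stratified by CpG content, 4 lists were called more and 4 less often marked. Odds ratios that turned direction stayed short of the threshold on both sides. With CpG strata these were forebrain (0.549), choroid plexus (1.19) and muscle (1.04). At −log10 q of at least 5 they were forebrain (0.494) and mesenchymal genes (0.541), with 1 start per gene forebrain (0.794) and mesenchymal genes (0.888), with 500 bp mesenchymal genes (0.954) and with 2500 bp astrocytes (1.44). In the replicate 1 and replicate 2 lists alone the odds ratios were 0.481 and 3.48 for oculomotor and serotonergic genes, 0.768 and 1.03 for mesenchymal genes, and 0.775 and 1.35 for astrocytes.

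The lists called narrower numbered 2 with 2500 bp, 2 in the pooled list, 8 with unmatched random lists, and 1 to 3 in the list of a single replicate. Width ratios that turned direction with unmatched random lists were dopaminergic (0.819), cell cycle (0.668), oligodendrocyte precursor (0.713), choroid plexus (0.655), late neuronal (0.634) and ribosomal genes (1.12), of which the cell cycle and late neuronal lists were called (adjusted permutation p = 0.0158 each). All other turned widths stayed short of the threshold. With 2500 bp they were oculomotor (1.00) and mesenchymal genes (1.04), in the pooled list oculomotor genes (1.00), and with 1 start per gene oculomotor genes (1.01) and endothelium (1.16). At −log10 q of at least 5 they were cell cycle (0.985), forebrain (1.10), mesenchymal (1.15) and late neuronal genes (0.981). In the replicate 1 and replicate 2 lists alone the ratios were 0.900 and 1.01 for cell cycle genes, 0.568 and 0.866 for oligodendrocyte precursor genes, 1.02 and 0.771 for myelinating oligodendrocyte genes, 0.906 and 1.33 for choroid plexus genes, and 0.788 and 1.05 for endothelium.

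Less frequent motifs numbered 0 in each of the 5 alternatives. The AP-1 odds ratio was 1.01 in each replicate's list and 1.04 with CpG-matched windows, where forkhead (0.933) and HNF4 (1.15) also turned and NFI stood at 1.00. The forkhead call was the only one of the 10 more frequent motifs lost in any alternative.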

Other observations

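The comparisons in this part were all chosen after related values had been seen. Wide peaks covered the 3 annotated genes of each of the neural microRNAs miR-124 and miR-9, which lie outside the protein-coding lists. Mir124a-1, Mir124a-2 and Mir124a-3, which encode the neuronal microRNA miR-124, lay inside peaks of 11342 bp (fold 41.6; chromosome 14, 64584889 to 64596230), 6478 bp (53.8; chromosome 3, 17792478 to 17798955) and 8344 bp (33.3; chromosome 2, 180888267 to 180896610). The Mir124a-2 peak had the highest fold of the replicated list. Mir9-1, Mir9-2 and Mir9-3, which encode miR-9, a microRNA of neural progenitors, lay inside peaks of 4982, 6150 and 11641 bp with folds of 16.3, 21.8 and 28.5. Of microRNA genes of other tissues, the liver's Mir122 lay 23837 bp from the nearest replicated peak, the muscle's Mir206 122361 bp and Mir133a-1 54335 bp, and the myeloid Mir223 146380 bp. Mir142 of blood cells lay 3022 bp from a peak of 5642 bp, and Mir1a-1 of muscle 2296 bp from a peak of 831 bp. Mir1a-2 of muscle lay 56907 bp and Mir192 of liver and gut 11077 bp from the nearest replicated peak. Mir375, known from endocrine cells, lay inside a peak of 777 bp with a fold of 4.31. Mir219a-1, a microRNA of oligodendrocytes, lay inside a peak of 1850 bp with a fold of 22.2, and Mirlet7b, of the let-7 family that the brain also expresses, lay 25853 bp from the nearest replicated peak. The peaks over Mir124a-1, Mir124a-2 and Mir9-3 were also the promoter peaks of the lincRNA genes Mir124a-1hg, Mir124-2hg and Mir9-3hg. The peak over Mir124a-3 was also that of the lincRNA genes Gm14342 and Gm27032. Otherwise the peaks were not checked for starts of neighbouring genes, so a peak over a microRNA gene can belong to another gene. Of all 322 microRNA genes with a promoter peak, only 73 lay over 5000 bp from any protein-coding start.

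Replicated promoter peaks were present at 883 of 5854 lincRNA genes (15.1%) and 1059 of 2959 antisense genes (35.8%), and no test compared them with protein-coding genes. Over 5000 bp from any protein-coding start these shares were 9.33% and 8.91%. Besides Mir124-2hg, C130071C03Rik (46.6) and Mir124a-1hg, Miat, a lincRNA of the nervous system, had a strong peak (31.4; chromosome 5, 112224759 to 112229537). Distal peaks over 5000 bp from any start were most numerous nearest to Gse1 (56 peaks), Zfhx3 (38), Zmiz1 (33) and Myt1l (27), the last a neuronal transcription factor gene. These counts were not adjusted for the length of sequence nearest to each gene, so they do not show a higher density of peaks.

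Genes on chromosome X were marked less often than autosomal genes, 454 of 948 (47.9%) against 13607 of 20780 (65.5%; odds ratio 0.485, 95% interval 0.425 to 0.552; Fisher's exact p = 2.99e-27, two-sided). The odds ratio stratified by CpG decile was 0.533 (Cochran-Mantel-Haenszel chi-square p = 1.48e-11). The median promoter fold of marked genes was 9.15 on X and 14.7 on the autosomes. The pools held embryos of both sexes, and neither comparison was adjusted for the copy number of X, so the cause of the difference was not tested. The replicated list held 4.70 peaks per Mb on X, and from 9.06 on chromosome 14 to 24.2 on chromosome 11 among the autosomes.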
